A study of Homo sapiens with 4 samples.

How the data were processed

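Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done for ONECUT2, a CUT-homeodomain transcription factor, in 22Rv1 cells, an established human prostate carcinoma line. Per the labels, the series holds 4 libraries: 2 ChIP libraries made with an antibody against ONECUT2 and 2 libraries of input DNA. The labels do not say whether the 2 ChIP libraries came from separate cultures, so differences between them may be technical. Per the labels' protocols, cells were cross-linked with formaldehyde, chromatin was sonicated, and libraries were sequenced on an Illumina HiSeq instrument.

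The submitters' processing notes name BWA 0.7.13-r1126, Picard, MACS2 2.1.1 and the genome build hg19, without saying which step each was used for. Per the file headers, which are track lines, the peaks of the 2 replicate lists came from MACS2. Per the labels, each list belongs to 1 ChIP library set against input. In these lists the authors gave each peak a fold enrichment, which is a ratio of the ChIP pileup at the summit to a local background from input. The authors also gave each peak a −log10 p-value and a −log10 q-value, as deposited. The smallest −log10 q was 1.32 in both lists. Peak calling settings and read filters were not given in the sources used here. Per the file headers, the third list is the optimal set of an irreproducible discovery rate (IDR) procedure. The procedure is meant to keep regions ranked alike in replicates, which the header does not show for each region of this list. The list has a deposited score from 705 to 1000 and a deposited signal value from 134 to 1470, a scale that the header does not name. The IDR list carries no p or q values, and the caller that made its regions was not given in the sources used here. Its header names no replicate, so the list has no replicate error of its own. How the libraries were combined in it was not given in the sources used here. All fold, p, q, score and signal values are the authors' own and were used to describe, rank or filter peaks.

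Positions are given in hg19 as the lists have them, counted from 1. Neither a genome sequence nor an annotation of this build was used here. Shares of peaks at promoters, recognition sequences under summits and the 11 gene lists fixed before the data were examined were therefore not analysed, and no gene was assigned to a peak. The regions named by rule are the 12 IDR regions of highest signal. The rule asked for a peak in both replicate lists at each, and all 12 had one. Other regions are named as chosen after their values were seen.

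MACS2 takes fold enrichment as (fragments + 1)/(background + 1) and p from the upper tail of a Poisson distribution. With these formulas the number of ChIP fragments at each summit and the background were recovered from fold and −log10 p. A whole number of fragments fitted within 0.001 on the −log10 p scale in 100% of the 14431 peaks of replicate 1 and 100% of the 11990 peaks of replicate 2. When the tail was taken 1 fragment off, 1.08% and 0.726% of peaks fitted. On simulated peaks made for each list, with 14431 and 11990 peaks, the step returned the exact fragment number in 100% of peaks. The simulated values were made with the same formulas, so this tests the inversion and not whether the formulas hold for the lists. Simulated backgrounds were also far below those recovered on mitochondrial DNA. The overlap step was tested on simulated positions on chromosome 2 of replicate 1, where it found 270 of 270 planted overlaps among 432 peaks.

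The median number of ChIP fragments at a summit was 34 in replicate 1 and 30 in replicate 2, and this number limits the precision of each fold value. Total read numbers were not given in the sources used here. The background had a smallest value of 4.37 fragments in replicate 1 and 4.87 in replicate 2, a ratio of 1.11. At 45 of the 45 peak pairs with the same summit position and a background above the smallest value, the 2 backgrounds stood in that ratio within 0.1%. Both lists were thus called against the same input background, and the 2 input libraries have no separate values here. Fold values of the replicates share this denominator.

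Peaks were called overlapping when they shared at least 1 bp. Shares have exact Clopper-Pearson intervals and counts per Mb have exact Poisson intervals, both at 95%. These intervals cover counting error only, since neighbouring peaks are not independent. Chance overlap was taken from 1000 circular shifts of the other list within each chromosome and, in a step added after the data were seen, from 1000 sets of shifts of each peak by 20 to 100 kb. Rank correlations are Spearman's rho over overlapping pairs, with each replicate 1 peak set against the overlapping replicate 2 peak of nearest summit. Intervals of rho came from 1000 bootstrap draws over pairs. The rho given by the shared background alone was estimated with 100 shuffles of the replicate 2 fragments among pairs of like background, in 20 classes. Densities per chromosome used the largest peak end over the 3 lists as the length, and chromosome 1 was split at its widest interval without peaks, from 121485181 to 142535523. That interval was left out of the lengths of the arms, while intervals without peaks on other chromosomes, unassembled sequence included, were kept, which lowers the densities of those chromosomes in comparison. Fisher's exact test, two-sided, compared peaks of fold enrichment below 6 with peaks of 6 or more, with Benjamini-Hochberg adjustment over chromosomes and arms. The calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. The overlaps, the rank correlation, the comparison with the IDR list and the density of IDR regions were fixed before the data were examined. The recovery of fragments, the shuffles, the classes of fold enrichment with their limit of 6, the split of chromosome 1 and Fisher's exact tests were chosen after the data were seen, so the p-values of those tests describe patterns already noticed. Alternatives covered the overlap rule, the threshold on q, the number of peaks kept, the chromosomes used, the value that was ranked and the replicate used.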

Results

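ONECUT2 occupancy was mapped in 22Rv1, a human castration-resistant prostate carcinoma cell line, with 2 ChIP libraries and 2 input libraries. Replicate 1 had 14431 peaks, replicate 2 had 11990, and the IDR list had 4297 regions. Median peak width was 317 bp in replicate 1, 294 bp in replicate 2 and 1768 bp in the IDR list. Most peaks were modest in height, with a median fold enrichment over input of 3.28 in replicate 1 and 3.41 in replicate 2. A fold enrichment of 6 or more was reached by 1077 peaks (7.46%) in replicate 1 and 849 peaks (7.08%) in replicate 2. The middle part of each list, from the 25th to the 75th percentile, had 24 to 45 ChIP fragments at the summit in replicate 1 and 22 to 43 in replicate 2.

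The first question was which regions had the highest IDR signal. The scale of that signal is not named, and it followed fragments more closely than fold enrichment. These regions therefore need not be the sites of strongest ONECUT2 occupancy. The 12 regions of highest IDR signal lay on chromosomes 7, 8, 11, 12, 16, 19, 20 and 22, with 3 of them on chromosome 19. Each had a peak in both replicate lists, with between 252 and 341 ChIP fragments at the summit. The region of highest signal (1470) lay on chromosome 16 from 1660152 to 1661849. Its fold enrichment was 14.6 ± 1.45 (SD, n = 2), with 308 fragments over a background of 18.7 in replicate 1 and 293 over 20.6 in replicate 2. A second region on chromosome 16, from 14013083 to 14015149, had a fold enrichment of 16.1 ± 2.83 (SD, n = 2). The region on chromosome 7 from 23509866 to 23511276 had a signal of 1455 and a fold enrichment of 12.2 ± 0.597 (SD, n = 2). On chromosome 12, the region from 123236700 to 123238119 had the lowest fold enrichment of the 12, at 9.04 ± 0.722 (SD, n = 2), and the most fragments in replicate 1, at 341. The 3 regions on chromosome 19 began at 42363595, 50168443 and 59068948 and ended at 42364934, 50170034 and 59071258. Their fold enrichments were 12.8 ± 2.43, 14.9 ± 0.892 and 11.1 ± 0.929 (SD, n = 2 each), in the same order. The region on chromosome 11 from 63605437 to 63607671 had the highest fold enrichment of the 12, at 16.4 ± 1.73 (SD, n = 2). The other region on chromosome 11, from 693985 to 696774, had 13.7 ± 2.85 (SD, n = 2), the widest difference between replicates among the 12. The remaining 3 regions lay on chromosome 22 from 51020308 to 51022234, on chromosome 8 from 28558031 to 28559809 and on chromosome 20 from 34329362 to 34331106. Their fold enrichments were 12.4 ± 0.942, 11.0 ± 1.23 and 13.9 ± 1.67 (SD, n = 2 each). Fold enrichment was higher in replicate 1 at 11 of the 12 regions.

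By fold enrichment, the best rank that any of these 12 regions reached was 38 in replicate 1 and 52 in replicate 2. The lowest of the 12, on chromosome 12, ranked 404 and 362. The 3 peak pairs of highest fold, chosen after their values were seen, lay over a lower background, at most 11.2 fragments in replicate 1 and 12.3 in replicate 2. Choosing by fold favours a low background by construction, since background is its denominator. On chromosome 4, the peak from 34923172 to 34925274 had a fold enrichment of 31.5 ± 0.957 (SD, n = 2), with 175 and 200 fragments in the replicates, and ranked 176 by IDR signal. On chromosome 8, the peak from 81876591 to 81878262 had 26.9 ± 4.54 (SD, n = 2) and ranked 83. On chromosome 17, the peak from 37616097 to 37619506 had 26.3 ± 2.64 (SD, n = 2), with 342 and 324 fragments, and ranked 14.

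Whether the 2 ChIP libraries marked the same places was asked next. In replicate 1, 7370 of 14431 peaks (51.1%, interval 50.3% to 51.9%) overlapped a replicate 2 peak. In replicate 2, 7739 of 11990 peaks (64.5%, interval 63.7% to 65.4%) overlapped a replicate 1 peak. Circular shifts gave a mean of 0.835% and at most 1.39% for replicate 1, and a mean of 0.959% and at most 2.60% for replicate 2. None of the 1000 shifts came near either observed share, so this one-sided permutation test gave p = 0.001 in both directions, the smallest that it can give. Libraries of the same cell line, called against the same input background, are bound to overlap more than shifted positions. The test therefore cannot tell ONECUT2 occupancy from calls that both libraries share for other reasons. Shifting each peak by 20 to 100 kb gave at most 1.52% and 1.76%. The shares fell to 29.7% and 35.8% when summits had to lie within 100 bp of each other.

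Overlap was highest for the strongest peaks. Of the replicate 1 peaks with a fold enrichment of 6 or more, 1075 of 1077 (99.8%, interval 99.3% to 100%) had a replicate 2 peak. In the other direction, 844 of 849 (99.4%, interval 98.6% to 99.8%) had a replicate 1 peak. All 365 replicate 1 peaks and all 239 replicate 2 peaks with a fold enrichment of 10 or more were shared. Among peaks with a fold enrichment from 3 to 4, 49.5% were shared in replicate 1 and 48.1% in replicate 2. From 4 to 6 the shares were 82.9% and 73.9%. Below 3 the lists differed, with 29.2% of replicate 1 peaks and 74.8% of replicate 2 peaks shared.

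**Figure D1:**
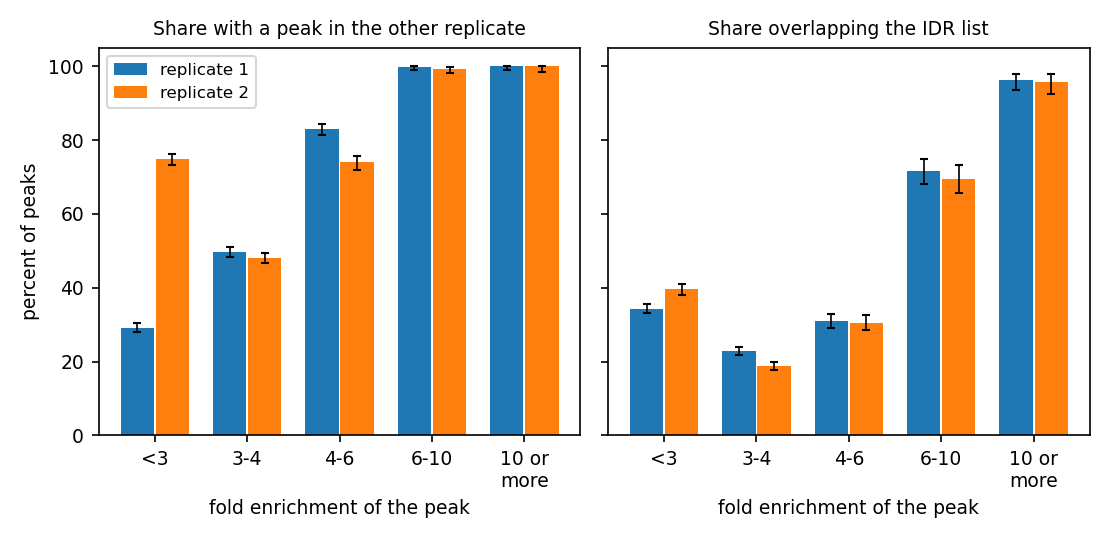
Percent of peaks in each class of fold enrichment that overlap a peak of the other replicate (left) or a region of the IDR list (right), for replicate 1 (blue) and replicate 2 (orange); error bars are exact 95% binomial intervals. At a fold enrichment of 10 or more every peak is shared, while 3 to 4 gives 49.5% and 48.1%.

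Over the 7370 overlapping pairs, fold enrichment had a rank correlation of 0.745 (bootstrap interval 0.733 to 0.756). Pairs are peaks within the same 2 libraries and not independent replicates. Shuffling the replicate 2 fragments among pairs of like background left a rho of 0.170 on average and 0.192 at most, which is the part that the shared input background can give as denominator. The shuffles do not measure other features that the libraries share, so the rest of rho need not be replicated binding. The median distance between summits was 79 bp, and 58.1% of pairs had summits within 100 bp. Fold enrichment was higher in replicate 1 in each class of pairs with summits within 100 bp. By mean fold enrichment, it was higher there in 776 of 1018 pairs below 3, in 1762 of 2476 from 3 to 6, in 425 of 526 from 6 to 10 and in 217 of 265 at 10 or more. The median log2 ratio of replicate 2 over replicate 1 was -0.21, -0.17, -0.28 and -0.24 in these classes. The mean log2 ratio of fragments was nearer to 0, at -0.06, -0.03, -0.10 and -0.07, while the smallest background of replicate 2 was 1.11 times that of replicate 1. The SD of the log2 ratio of fragments was 0.23, 0.30, 0.29 and 0.25, against 0.32, 0.35, 0.24 and 0.18 from counting error. Only pairs called in both lists with summits within 100 bp were counted, which can narrow this spread, most of all near the calling threshold. An SD below counting error therefore does not show that weak peaks agree better than counting allows.

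**Figure D2:**
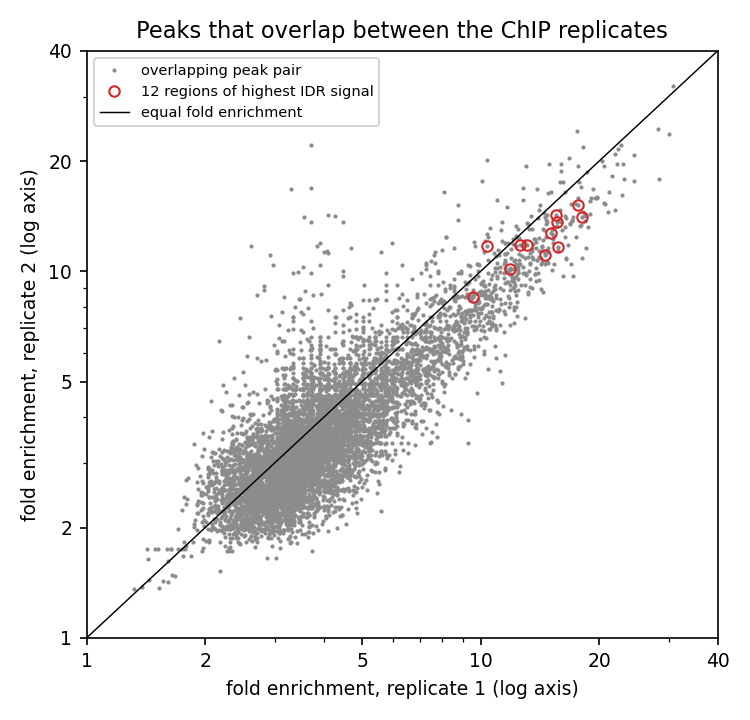
Fold enrichment over input in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis) for 7370 overlapping peak pairs (grey points), with the 12 regions of highest IDR signal circled in red and a line of equal values. Of the circled regions, 11 lie below the line, with higher values in replicate 1.

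Which sites the IDR list keeps was then examined. Of its 4297 regions, 2721 (63.3%, interval 61.9% to 64.8%) overlapped peaks in both replicates, 669 in replicate 1 only and 121 in replicate 2 only. The other 786 regions (18.3%, interval 17.1% to 19.5%) overlapped no peak of either list. Regions with a peak in both lists made up 92.1% of the 1074 regions of highest signal and 39.0% of the 1075 regions of lowest signal. In turn, 32.8% of replicate 1 peaks and 31.4% of replicate 2 peaks fell in the IDR list.

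Among peaks with a fold enrichment of 10 or more, 351 of 365 in replicate 1 (96.2%) and 229 of 239 in replicate 2 (95.8%) were in the IDR list. Across whole lists the median fold enrichment of peaks inside and outside the IDR list was nearly equal. It was 3.30 inside and 3.27 outside in replicate 1, a ratio of 1.01, and 3.34 and 3.41 in replicate 2, a ratio of 0.980. When a peak and an IDR region each had to cover 50% of the other, the ratios became 1.87 and 1.78. The number of fragments differed more, with medians of 45 inside and 30 outside in replicate 1 and 44 and 25 in replicate 2. Background was also higher inside, at 13.1 fragments against 8.39 in replicate 1 and 13.2 against 5.86 in replicate 2.

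IDR regions were spread unevenly over chromosomes. The mean density of IDR regions over the autosomes and X was 1.43 per Mb. Chromosome 19, known as the most gene-dense human chromosome, had the highest density, with 233 regions or 3.94 per Mb (interval 3.45 to 4.48). Among the autosomes and X, the only chromosomes compared, X had the lowest, with 30 regions or 0.194 per Mb (interval 0.131 to 0.278). Relative to the mean density, X stood at 0.136 in the IDR list, 0.261 in replicate 1 and 0.208 in replicate 2. The 90th percentile of background under peaks on X was 0.544 and 0.565 times the median of the autosomes other than 7, 12 and the long arm of 1. The counts are of called regions, so the low density of X need not mean that few sites were occupied there. High densities were also found on the long arm of chromosome 1 (3.54 per Mb, interval 3.20 to 3.92), chromosome 12 (3.13, interval 2.84 to 3.45), chromosome 17 (2.84, interval 2.48 to 3.23) and chromosome 7 (2.69, interval 2.44 to 2.95). The short arm of chromosome 1 had 1.70 per Mb (interval 1.48 to 1.95). Chromosomes 21, 13 and 18 had 0.687 (interval 0.473 to 0.964), 0.713 (interval 0.567 to 0.884) and 0.809 per Mb (interval 0.622 to 1.04), which their intervals do not set apart. Lengths include stretches without peaks on every chromosome except between the arms of chromosome 1. Among all replicate 1 peaks, chromosome 19 had 13.5 per Mb, against 9.31 on the long arm of chromosome 1 and 8.76 on chromosome 12. The order turned in replicate 2, with 8.58 on chromosome 19 against 9.40 on that arm and 9.12 on chromosome 12.

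The mean density of replicate peaks with a fold enrichment of 6 or more was 0.355 per Mb in replicate 1 and 0.281 in replicate 2. Chromosome 19 had 1.25 per Mb in replicate 1 (interval 0.983 to 1.57) and 0.863 in replicate 2 (interval 0.643 to 1.13). Chromosome 17 followed, with 0.802 (interval 0.619 to 1.02) and 0.580 (interval 0.426 to 0.771). Chromosome 12 had 0.531 (interval 0.414 to 0.669) and 0.419 (interval 0.316 to 0.544), and the long arm of chromosome 1 had 0.525 (interval 0.397 to 0.682) and 0.441 (interval 0.324 to 0.586), intervals above the means. Chromosome 7 had 0.378 (interval 0.289 to 0.487) and 0.321 (interval 0.239 to 0.423), intervals that include the means. Chromosome X had 0.220 (interval 0.153 to 0.308) and 0.169 (interval 0.110 to 0.247), intervals below the means.

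On chromosome 7 there were 18.6 peaks below a fold enrichment of 6 for each peak at or above it in replicate 1, against 12.2 on the other autosomes. By Fisher's exact test the odds ratio was 1.53 in replicate 1 (interval 1.17 to 2.03, adjusted p = 0.0284) and 1.92 in replicate 2 (interval 1.43 to 2.61, adjusted p = 5.28e-05). For chromosome 12 it was 1.26 (interval 0.979 to 1.64, adjusted exact p = 0.270) and 1.63 (interval 1.24 to 2.20, adjusted p = 0.00222). For the long arm of chromosome 1 it was 1.36 (interval 1.03 to 1.83, adjusted exact p = 0.208) and 1.58 (interval 1.17 to 2.19, adjusted p = 0.0107). Chromosome 17 went the other way, with 0.651 (interval 0.498 to 0.863, adjusted exact p = 0.0284) and 0.540 (interval 0.393 to 0.755, adjusted p = 0.00222). In replicate 2 the same test gave 0.659 for chromosome 19 (interval 0.488 to 0.907, adjusted exact p = 0.0365) and 0.625 for chromosome 10 (interval 0.451 to 0.886, adjusted exact p = 0.0333). In replicate 1 these were 0.764 (interval 0.595 to 0.993, adjusted exact p = 0.208) and 0.785 (interval 0.586 to 1.07, adjusted exact p = 0.344). These tests treat each peak as 1 observation and compare places within the 2 libraries.

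**Figure D3:**
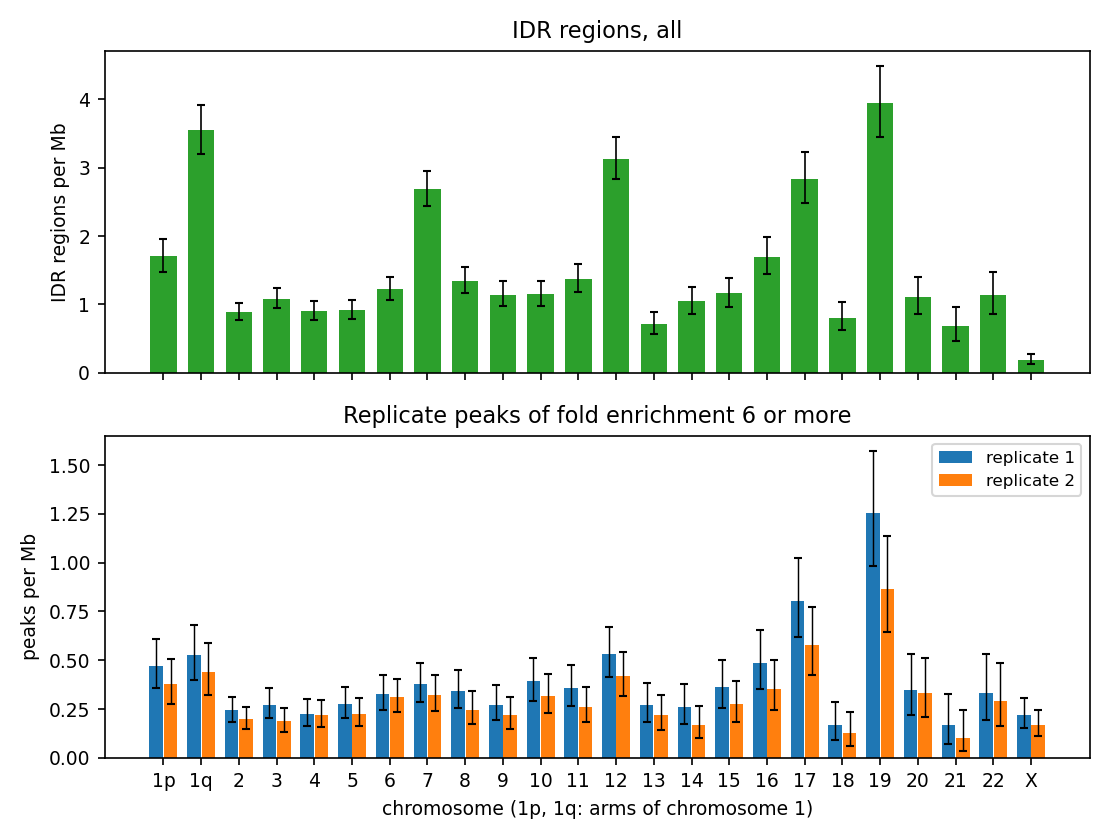
Density per Mb along chromosomes of all IDR regions (top) and of replicate peaks with a fold enrichment of 6 or more (bottom; blue, replicate 1; orange, replicate 2), with exact 95% Poisson intervals as error bars. Chromosome 19 is highest in both panels, at 3.94 IDR regions per Mb, while chromosomes 7 and 12 and the long arm of chromosome 1 stand out in the upper panel more than in the lower.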

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

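The alternatives without chromosomes 7, 12 and 1q, with a fold enrichment of 6 or more, with ranked or compared fragments, and with summits inside IDR regions were chosen after seeing the data. Over 34 alternative values, 9 stayed within the interval or replicate spread of their result and 25 did not; the causes were not tested unless stated. The shares of overlapping peaks (51.1% for replicate 1, 64.5% for replicate 2) became 32.4% and 39.0% with a reciprocal overlap of 50%, 29.7% and 35.8% with summits within 100 bp, and 52.4% and 68.6% with −log10 q of at least 5. They were 57.8% and 57.2% among the 5000 peaks of highest fold and 99.8% and 99.4% at a fold of 6 or more. Leaving out chromosomes 7, 12 and 1q gave 69.4% for replicate 2. The rank correlation of fold (0.745) was 0.816 with reciprocal overlap, 0.837 with summits within 100 bp, 0.809 with −log10 q of at least 5, 0.618 for −log10 p and 0.872 for fragments. Background itself had a rank correlation of 0.932 over the pairs. The shuffles were run for fold only, so the part of 0.872 that the shared background gives is not known. The fold ratio of IDR to other peaks became 1.87 and 1.78 with reciprocal overlap, which by construction keeps wide peaks (median widths 1166 and 1082 bp), and 1.50 and 1.76 for fragments. Density relative to all chromosomes, from 1 replicate list alone, ranged from 2.19 to 2.85 on chromosome 19 (IDR list 2.76), 0.208 to 0.261 on X (0.136), 1.86 to 2.32 on 12 (2.20) and 1.57 to 2.06 on 7 (1.88). No paired analysis was possible because each list already sets a ChIP library against 1 common input background. Overlaps and correlations need both replicates, so neither could be left out. Settings listed beforehand for promoters, recognition sequences and gene lists were not run, for want of an hg19 genome and annotation. Fragment numbers had medians of 34 and 30. In pairs with summits within 100 bp, counting error of the log2 ratio was larger below a mean fold of 6 (0.32 and 0.35) than above it (0.24 and 0.18).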

Other observations

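All tests in this part were chosen after the results were seen. Windows of 1 Mb with many peaks were counted in the same way. In replicate 1 the most peaks, 54 in each, lay on chromosome 19 from 58 to 59 Mb and on chromosome 6 from 27 to 28 Mb, and replicate 2 had 38 and 42 there. The neighbouring window on chromosome 6, from 26 to 27 Mb, had 46 and 40. As background, this part of chromosome 6 is known for a large cluster of histone genes, and the distal end of chromosome 19 for zinc-finger genes. Peaks of fold enrichment 6 or more numbered 3 and 2 in the chromosome 19 window, 0 and 2 in the chromosome 6 window from 27 to 28 Mb and 6 and 4 in its neighbour, against 7.46% and 7.08% of all peaks. The IDR list kept 11 regions there and 7 in the chromosome 6 window from 27 to 28 Mb. Its own densest window, with 20 regions, was on chromosome 1 from 145 to 146 Mb.

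In replicate 2 the densest windows lay elsewhere, on chromosome 12 from 71 to 72 Mb with 57 peaks and on chromosome 1 from 192 to 193 Mb with 55. Replicate 1 had 44 and 27 peaks in these windows. The median background of the peaks was at the smallest value of each list, 4.37 and 4.87 fragments, and each replicate had 1 peak of fold enrichment 6 or more in the chromosome 12 window and 2 in the chromosome 1 window. Sequences without a set position on a chromosome, some of them assigned to a named chromosome, held 200 peaks in replicate 1 and 170 in replicate 2. Of these peaks, 66.0% and 85.3% were shared with the other replicate, and none of the IDR regions lay on such sequences.

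Chromosomes 7 and 12 and the long arm of chromosome 1 made up 13.3% of the length and held 23.2% of replicate 1 peaks, 29.2% of replicate 2 peaks and 28.5% of IDR regions. Peaks below a fold enrichment of 6 were in excess over stronger ones there, with odds ratios of 1.45 and 1.92 (intervals 1.23 to 1.72 and 1.60 to 2.32). That cannot decide on a higher density of sites, since the segments were picked for their many peaks, most of them below 6. The comparison group also held dense chromosomes that went the other way, 17 (odds ratios 0.651 and 0.540) and 19 (0.764 and 0.659). Random calls do not account for the whole excess, since 50.6% and 50.7% of the weaker peaks there overlapped the other replicate, against 24.3% and 25.4% if all weaker peaks above the density of other autosomes were random; on other autosomes the shares were 45.8% and 66.2%, so in replicate 2 a part may be random, and the shared input leaves room for the same false calls in both. Extra genome copies remain a candidate explanation for peaks above the smallest background. The 90th percentile of background of these peaks was 1.35 and 1.30 times that of other autosomes. Each of the segments lay above every other autosome and the short arm of chromosome 1. The lowest segment had 22.999 fragments in replicate 1, against at most 18.4 elsewhere, and 23.1 in replicate 2, against at most 20.5. The ratio of medians was 1.18 and 0.868, however, so extra copies cannot be told apart from a change in the mix of peaks. Peaks at the smallest background were more frequent there than on other autosomes (21.8% against 14.6%, odds ratio 1.64, and 32.6% against 25.6%, odds ratio 1.41), which leaves extra copies open too, since that background is 1 value for the whole genome while ChIP fragments could rise with copies; apart from the density of sites, no biological explanation was tested.

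IDR signal followed fold enrichment less closely than fragments. Its rank correlation was 0.444 and 0.394 with fold enrichment and 0.624 and 0.663 with fragments in the replicates, a difference of 0.180 (interval 0.152 to 0.205) and 0.269 (interval 0.241 to 0.296), which is consistent with a ranking closer to read number. The 786 regions without a replicate peak were mostly weak, since the probability that such a region had a lower signal than a region with peaks in both lists was 0.797. Their highest signal was 335, and 39.9% of them lay on chromosomes 7, 12 and 1q. The caller behind the list stays open, and no biological explanation was tested.

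Mitochondrial DNA carried 5 IDR regions, of which the strongest, from 10150 to 14459, ranked 79 with a signal of 791. The replicate lists had 16 and 10 peaks there, with fold enrichments from 1.32 to 2.03 and from 1.36 to 1.99. Their median background was 17.4 and 25.1 times that of nuclear peaks, and their highest fold lay below the 10th percentile of nuclear peaks (2.35 and 2.40). A high number of mitochondrial genomes, at which small differences between ChIP and input pass the threshold, may therefore account for these regions; no biological explanation was tested.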
